A study of Mus musculus with 4 samples.

How the data were processed

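The series held 4 two-colour microarrays of RNA from the dentate gyrus of the hippocampus of young male C57BL/6J mice, 1 array for each of 4 times, 1, 2, 4 and 6 h. Per the labels, each array set RNA of mice injected with saline (5 µL per g body weight), labelled with Cy3, against RNA of mice injected with MK-801 (300 µg per g body weight), labelled with Cy5. MK-801 (dizocilpine) is a blocker of the NMDA-type glutamate receptor channel. The dose is printed as the labels give it. It is far above the doses commonly given to mice, and an error of unit in the labels is not excluded. The labels count the times from a last shock given to the MK-801 mice and describe the RNA of both channels as that of control mice, so whether the injected mice of these arrays were shocked is not settled. No label says how many mice were pooled. No array repeated a time or turned the dyes around.

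The deposited values are log ratios of the channels of each array, read here as log2, in 1 table for the series. How the authors scanned, background-corrected and normalised the arrays is not given in the sources used here. The log base is not stated either. Base 2 is the working reading, and natural logarithms are not excluded, in which case every size given here as log2 would have to be multiplied by a constant above 1. The direction of the ratio is also unstated: a positive value may stand for more RNA in the MK-801 channel (Cy5 over Cy3) or in the saline channel (Cy3 over Cy5). Results are therefore given by the sign of the deposited value, with no statement of which treatment was higher, and all 4 arrays are taken to run the same way because their labels are worded alike. The medians of the deposited non-zero values were 0.0074 at 1 h, 0.0093 at 2 h, 0.017 at 4 h and 0.0052 at 6 h, so the authors' values were already centred near 0.

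An exact 0 filled 25.5%, 24.9%, 37.4% and 35.4% of the 16281 features at 1, 2, 4 and 6 h, while no other value occurred more than 3 times on an array. Exact 0 was therefore treated as no value. This left 12131, 12227, 10185 and 10512 features with a value, and 8777 with a value on all 4 arrays. No intensities were used here, so signal over background, dye effects that depend on intensity and saturation could not be examined. The number of arrays limits the precision.

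Features were named through the platform annotation paired with the table, with symbols checked against the gene table of assembly GRCm38.p6 by Entrez identifier. Of the 16281 features, 13738 had 1 gene symbol, 52 had several and 2491 had none. The identifiers of 13694 features matched, and 0 symbols changed. Only features with 1 symbol and a value on all 4 arrays entered the tests. These were 7684 features of 6661 genes. Each array was centred on its median, and the 938 genes with several features were given the mean of their features. For some named genes whose features differed, the text gives the values of single features.

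With 1 array per time no time can be tested on its own. In limma 3.58.1 under R 4.3.3, lmFit and eBayes were used for 3 tests, each two-sided with Benjamini-Hochberg adjustment at 0.05. The mean of the 4 log2 ratios was tested against 0, with the spread between times as the error. The slope on log2 hours was tested with an intercept. The 4 and 6 h arrays were tested against the 1 and 2 h arrays, with neighbouring times standing in for replicates. P-values measure the spread between arrays of different times, which holds both technical and biological spread. A dye bias of a gene is in all 4 arrays: it is confounded with treatment in the mean, and a constant one cancels in the slope and in late against early times. At each time the genes past an absolute log2 ratio of 1 (2 times) were counted, with the overlap between times and the overlap that independent lists of those sizes would give.

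A set of 32 gene lists with at least 5 measured genes was tested with camera on the mean, with a preset correlation between genes of 0.01, and camera with an estimated correlation and fry were run beside it. Camera on the slope was added after the values of a few genes had been seen. For each array a list's median was placed among the medians of 10000 random lists of the same size. These could not be matched on level, since the table holds ratios alone. The lists, the tests, most alternative settings and the rule for named genes were chosen before the data were examined. The rule named 10 positive and 10 negative genes of the mean fit, filled where none passed from genes with the same sign on all 4 arrays ranked by their smallest absolute ratio. It also took the 3 highest and 3 lowest genes at each time, the 5 genes of smallest unadjusted p in each direction of the slope where none passed after adjustment, and the 3 members of each list with the largest absolute mean. Always included, where measured on all 4 arrays, were Fos, Junb, Egr1, Arc, Npas4, Bdnf, Nr4a1, Homer1, Dusp1, Grin1, Grin2a, Grin2b, Fkbp5, Sgk1 and Prox1. Npas4 and Grin1 did not have a value on all 4 arrays.

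The fits were tested on simulated data for 6661 genes with 200 changed genes. The simulated arrays were independent, with the spread left around the slope on log2 hours in all 3 fits. Spread between times that the slope takes up is therefore missing for the mean and for late against early times. The shares recovered in those fits can be too high for the real arrays. In the mean fit 71% of genes with a simulated log2 size of 0.5 and 98.5% of those with a size of 1 were recovered. The slope fit recovered 71% and 99% at slopes of 0.5 and 1 per doubling of time, and late against early times recovered 0% at a size of 0.5 and 76% at 1. Alternatives covered centring, equal spread of the arrays, the filter on missing values, a robust prior, array weights, features on their own, quantile normalisation, no moderation, linear hours, the set test, the size threshold and each array left out in turn. Added after seeing the data were exact 0 read as a value, leaving out features at or under -1.5, 1 feature per gene, and leaving out the 1 h array together with the low features. Correlations, random placements and figures were made in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.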

Results

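The data were log ratios from 4 two-colour arrays that compared dentate gyrus RNA of MK-801 mice with that of saline mice at 1, 2, 4 and 6 h, 1 array per time. The dentate gyrus is the part of the hippocampus whose main neurons are the granule cells, and MK-801 blocks NMDA receptors. All values below are centred log ratios read as log2, and their sign is that of the deposited table. Whether positive means more RNA in the MK-801 or in the saline channel is not stated, and a statement about positive values holds for either reading with the treatments exchanged. Values were available for 6661 named genes on all 4 arrays. There is no repeat of any time, so a value at 1 time has no replicate error of its own. Within an array, 15 features of Gapdh, a glycolytic enzyme, gave -0.26 ± 0.09 at 1 h, 0.47 ± 0.14 at 2 h, 0.39 ± 0.03 at 4 h and 0.35 ± 0.06 at 6 h (mean ± SD over features). That spread covers features of 1 array and leaves out the spread between mice.

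The first comparison concerned log ratios shared by the 4 times. Among genes positive on all 4 arrays, those with the largest smallest ratio over the arrays included Ccl28, a chemokine (mean 0.36 ± 0.03, SD over the 4 arrays), Atp6v1a, a subunit of the vacuolar proton pump (0.28 ± 0.01), Babam1 (0.31 ± 0.03), Qdpr, which regenerates the cofactor of aromatic amino acid hydroxylases (0.31 ± 0.03), Chn1, a Rac GTPase-activating protein of neurons (0.41 ± 0.07), and Tmem167 (0.35 ± 0.07). Gch1, the first enzyme of tetrahydrobiopterin synthesis (0.36 ± 0.12), Pdcl (0.36 ± 0.12), Coasy, an enzyme of coenzyme A synthesis (0.44 ± 0.15), and Pdlim5 (0.56 ± 0.24) completed these 10 positive genes of the rule. Other features of Pdlim5, Atp6v1a and Ccl28, without values on all 4 arrays, read otherwise: those of Pdlim5 gave -1.19 at 1 h in 1 case and -0.42 at 2 h in another, and that of Atp6v1a gave -0.87 at 4 h and -1.15 at 6 h, and that of Ccl28 gave 0.06 at 4 h. With values on at least 3 arrays the mean of Pdlim5 turned to -0.0099, and with exact 0 read as a value that of Atp6v1a turned to -0.11 and those of Pdlim5 and Ccl28 became 0.02 and 0.19. The clock gene Per1 was negative on every array, at -0.45, -0.48, -0.46 and -0.42 at 1, 2, 4 and 6 h, and its 2 features were both negative on every array. None of these genes passed the test with equal weights. limma placed 0 of 6661 genes past an adjusted p of 0.05, with 976 at an unadjusted p under 0.05 (456 positive, 520 negative) and a lowest adjusted p of 0.167. With array weights, which let arrays count unequally, 1793 genes passed (932 positive, 861 negative), among them the 10 positive genes above, with adjusted p between 0.00285 and 0.00972. These 10 were picked from the same arrays for ratios of the same sign, so their passing adds no separate support.

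The 10 negative genes of the rule had much larger ratios. They were Sdc3, a heparan sulfate proteoglycan (-1.75, -3.35, -3.84 and -3.25 at 1, 2, 4 and 6 h), the non-coding RNA Xist (-1.20, -3.55, -4.18 and -3.55), the transcription factors Hes1 (mean -2.86 ± 1.14), Lhx1 (-2.80 ± 1.09), Atf2 (-2.49 ± 1.33) and Rora (-1.58 ± 0.68), and Nfkbib (-2.58 ± 1.12), Pgpep1 (-2.67 ± 1.23), Scd1 (-1.76 ± 0.76) and Igfbpl1 (-1.42 ± 0.44). Their adjusted p in limma lay between 0.167 for Sdc3 and 0.237 for Atf2. Each rested on 1 feature with values on all 4 arrays, and 5 of these features, those of Nfkbib, Hes1, Lhx1, Sdc3 and Rora, had feature numbers between 15762 and 15772. The features of Igfbpl1 and Atf2 had numbers not far below, 15720 and 15630, while those of Pgpep1, Xist and Scd1 lay elsewhere (7451, 17648 and 17738). A second feature of Xist gave 0.26 at 1 h and 0.41 at 2 h, and a second feature of Atf2 gave -0.03 at 2 h, 0.31 at 4 h and 0.26 at 6 h, so the low ratios of these genes were not shared by their other features. The mean of Atf2 became -1.26 with values on at least 3 arrays, and with exact 0 read as a value those of Xist and Atf2 became -1.48 and -1.18. With array weights these 10 genes, also picked from the same arrays, passed as well (adjusted p 0.000345 to 0.00137). With quantile normalisation Sdc3, Hes1, Lhx1, Xist, Nfkbib, Pgpep1 and Igfbpl1 passed (adjusted p 3.88e-05 for Sdc3 to 0.0334 for Igfbpl1), and Sdc3 passed with values on at least 3 arrays (0.0476).

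The 1 h array stood apart from the other 3. Over 8735 features, with features at or under -1.5 left out, its ratios correlated at r = -0.13 with those at 2 h, -0.15 at 4 h and -0.15 at 6 h, while the correlation was 0.46 between 2 and 4 h, 0.53 between 2 and 6 h and 0.70 between 4 and 6 h (Pearson, across features, which are not independent replicates). Without the 1 h array limma placed 856 genes past the threshold, 463 positive and 393 negative, and without any other array it placed 0. At 1 h, 154 of these 463 positive genes and 156 of the 393 negative genes had the same sign, where of all genes with a positive or a negative mean over the later times 40.5% and 50.0% had the same sign at 1 h. The 20 genes of the rule passed without the 1 h array, but they were picked for ratios of the same sign on these arrays. Gapdh was called in that fit as well, with an adjusted p of 0.0194, together with Suclg2 and Mdh1 of the citric acid cycle (adjusted p 0.00895 and 0.0151, both positive, while Dlst of that cycle was negative at 0.0479), the presynaptic genes Rab3b and Stx1a (0.0108 and 0.0138), and the astrocyte genes Aldoc, Gfap and Slc1a3 (0.0258, 0.0212 and 0.0256). These classes as wholes had 3 of 12 citric acid cycle genes, 2 of 20 synaptic vesicle genes and 4 of 24 astrocyte markers called, beside the 856 of 6661 genes overall. Of these, Aldoc alone had a positive value at 1 h (0.06), and the values of the others at 1 h ran from -0.52 for Suclg2 to -0.09 for Slc1a3.

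**Figure D1:**
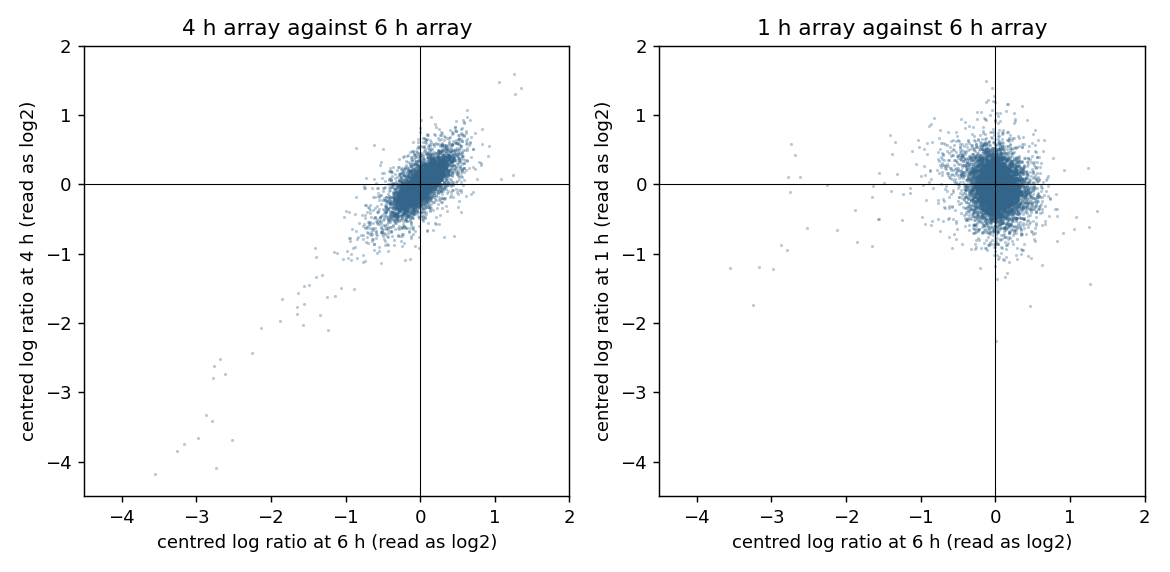
Each point is 1 of 6661 genes. The left panel sets the centred log ratio at 4 h (vertical) against that at 6 h (horizontal), and the right panel sets the 1 h array against 6 h; all axes are read as log2. Genes at 4 and 6 h follow each other (r = 0.79 over genes), and genes at 1 and 6 h do not (r = -0.08).

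Immediate early genes, which neurons switch on within minutes of activity, were the list with the smallest p for a slope with time. Their median over 34 genes was 0.25 at 1 h, -0.08 at 2 h, -0.21 at 4 h and -0.14 at 6 h, and 25, 8, 6 and 11 of the 34 were positive. Among 10000 random lists these medians lay at percentiles 100, 2.88, 0 and 0. The transcription factor Nr4a1 had ratios of 0.63, -0.13, -0.28 and -0.36 at 1, 2, 4 and 6 h. Junb had 0.35, -0.24, -0.29 and -0.24, and Egr1 had 0.16, -0.37, -0.68 and -0.53. Arc, a synaptic protein, had 0.51, -0.01, -0.21 and -0.19. The phosphatase Dusp1 had 0.41, 0.00, -0.22 and -0.35, and both of its features ran from above 0.36 at 1 h to below -0.34 at 6 h. Fos averaged 0.64, -0.52, -0.58 and -0.50, but its features differed: one read 1.17, -1.06, -1.17 and -1.01, and the other 0.11, 0.02, 0.01 and 0.02. Nr4a2 read -0.86, -0.85, 0.12 and -0.09, while another of its features, without a value at 2 h, read -0.32, -0.02 and -0.19 at 1, 4 and 6 h. Per1, also in the list, stayed negative throughout. The 2 Bdnf features differed at 1 h (0.00 and 0.73), and the 4 Homer1 features ran from -0.50 to 0.61 there.

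The slope of this list was negative (camera, adjusted p = 0.000795 over 32 lists), and 25 of its 34 slopes were below 0. The call was lost with an estimated correlation between genes (adjusted p = 0.793), and also without the 1 h array (adjusted p = 0.93), so the trend rests on the step from 1 h to the later times. No single member passed in the slope fit, with 14 of 34 at an unadjusted p under 0.05, 0 over all genes and 0 adjusted over the list alone. For the mean over the 4 times 0 members passed over all genes and 2 passed adjusted over the list alone. Without the 1 h array 9 members passed over all genes, all negative, and 12 passed adjusted over the list alone, with camera at an adjusted p of 0.00533 (0.703 with an estimated correlation). The granule cell markers, listed to follow the tissue taken, had medians of -0.08, -0.13, -0.08 and -0.03 at 1, 2, 4 and 6 h. Blood markers ran in the same direction as the immediate early genes, with medians of 0.27, 0.06, -0.09 and -0.09 and 7 of 7 genes positive at 1 h (slope, adjusted p = 0.189, camera), and vessel markers ran in the opposite direction, from -0.20 at 1 h to 0.11 at 4 h.

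**Figure D2:**
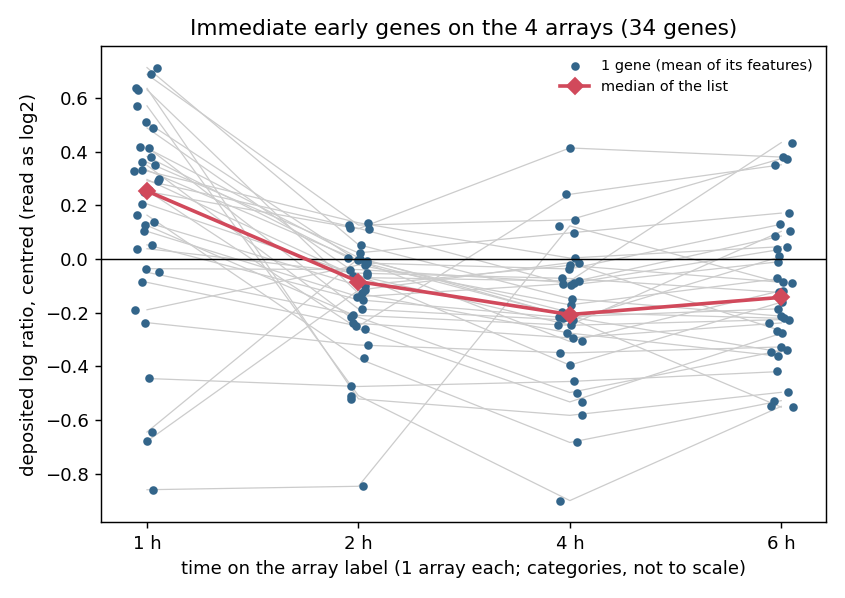
Each point is the centred log ratio (vertical axis, read as log2) of 1 of the 34 immediate early genes on the array of the time on the horizontal axis, grey lines join a gene across arrays, and diamonds give the median. The median is 0.25 at 1 h and lies between -0.08 and -0.21 at the later times.

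Over single genes, limma placed 0 of 6661 slopes past the threshold, with 1060 at an unadjusted p under 0.05 (614 positive, 446 negative) and a lowest adjusted p of 0.255. Without the 6 h array 12 slopes passed. The smallest unadjusted p among positive slopes belonged to Tex47, whose ratios were -1.43, -0.56, 1.31 and 1.27 at 1, 2, 4 and 6 h (slope 1.16 ± 0.14 per doubling of time, SE). It was followed by the small heat shock protein gene Hspb3 (-0.70 at 1 h and 0.91 at 6 h), Nmral1 (-0.35 and 0.83), Gas8, a gene of the ciliary dynein regulator (-0.46 and 0.83), and Ctnnal1 (-0.81 and 0.82). Among negative slopes they were Mospd4 (0.48 at 1 h and -1.12 at 6 h), Fabp2, a fatty acid binding protein (0.71 and -1.41), Supt4a (0.16 and -1.32), Rora (-0.66 and -2.13) and Angptl1 (0.96 and -0.82). Between late and early times limma placed 0 of 6661 genes past the threshold, with 383 at an unadjusted p under 0.05 (235 higher and 148 lower late) and a lowest adjusted p of 0.171. Without the 2 h array 1329 passed, but 1 h alone then stood for early times, was assumed to vary like the late arrays, and the spread came from the 4 and 6 h arrays alone.

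At single times, 18 genes lay at or above 1 and 26 at or below -1 at 1 h, 0 and 44 at 2 h, 5 and 43 at 4 h, and 6 and 36 at 6 h. With the arrays brought to equal spread these counts were 2 and 6 at 1 h, 0 and 47 at 2 h, 11 and 52 at 4 h, and 8 and 55 at 6 h, so the order of 1 h and 4 h for positive genes depends on the spread of the arrays. Both sets of counts cover named genes with values on all 4 arrays. Among all features with a value at 1 h, 209 deposited values lay above 1 and 48 below -1, the opposite balance. The lean to negative genes at 1 h thus depends on which features enter. At 2, 4 and 6 h more features lay below -1 than above 1 before this filter too. Among the genes with values on all 4 arrays, the highest at 1 h were Alpl, a phosphatase (1.49), Hoxa7 (1.39) and Snx15 (1.28), and the lowest were Crim1 (-2.26), the neuropeptide gene Nts (-1.75) and Sdc3 (-1.75). None of Alpl, Hoxa7, Snx15, Crim1 and Nts kept a ratio past 1 in either direction at a later time. At 2 h the highest were Arap1 (0.91), the clock output gene Tef (0.84) and Icam4 (0.80). At 4 h they were Cat, the peroxide-degrading enzyme catalase (1.59), the linker histone gene H1f4 (1.48) and Vdac1, the channel of the outer mitochondrial membrane (1.40), and at 6 h Vdac1 (1.36), Tex47 (1.27) and Cat (1.25). Cat read -0.61 at 1 h and -0.76 at 2 h. A second Vdac1 feature had a value at 1 h alone, 0.55, where the first read -0.38. The lowest genes at 2 h were Pgpep1, Xist and Hes1, at 4 h Xist, Car1 (-4.09, against 0.59 at 1 h) and Sdc3, and at 6 h Xist, Sdc3 and Hes1. The Car1 feature had number 15631, next to the low Atf2 feature with number 15630. Of the genes at or below -1, 29 were shared by 2 and 4 h, 29 by 2 and 6 h and 32 by 4 and 6 h, where independent lists would share 0.28, 0.24 and 0.23. With 1 h, 4 were shared at each later time, where independent lists would share 0.17 at 2 h, 0.17 at 4 h and 0.14 at 6 h. These 4 were Sdc3, Lhx1, Xist and Hes1 each time, and each rested on 1 feature with values on all 4 arrays. The features of Hes1, Lhx1 and Sdc3 had nearby numbers (15763, 15764 and 15769), and a second Xist feature was positive at 1 and 2 h (0.26 and 0.41).

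Of the 32 lists, 7 passed in camera on the mean over the 4 times, and 0 passed with an estimated correlation. Positive lists were heat shock proteins and chaperones (adjusted p = 0.00595, 0.53 with an estimated correlation), oxidative phosphorylation (0.00595, 0.723), proteasome (0.00595, 0.53), antioxidant and metallothionein genes (0.00595, 0.53), cytosolic ribosomal proteins (0.0244, 0.801) and protein phosphatase and MAP kinase pathway genes (0.045, 0.801). Leaving out single arrays ended 5 of the 7 calls: heat shock proteins without 1 h (adjusted p = 0.27), oxidative phosphorylation without 1 h (0.051), ribosomal proteins without 1 h (0.30) or 2 h (0.13), the phosphatase and kinase list without 2 h (0.14), 4 h (0.13) or 6 h (0.12), and the choroid plexus markers without 2 h (0.17). The median mean ratios of the positive lists were small, at 0.10, 0.05, 0.12, 0.13, 0.04 and 0.09. None of their members passed alone over all genes, and adjusted over the list alone 4 antioxidant genes did and 0 members of the other 5 lists. Proteasome subunits had positive medians on every array (0.07, 0.06, 0.07 and 0.10 at 1, 2, 4 and 6 h), with Psmb6 at a mean of 0.27 ± 0.07, Psmb4 at 0.29 ± 0.11 and Psmc3 at 0.34 ± 0.24. In oxidative phosphorylation the respiratory chain gene Cox5b had a mean of 0.32 ± 0.08, and among ribosomal proteins Rpl29 had 0.27 ± 0.11.

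The heat shock list was highest at 1 h, with a median of 0.18 and 30 of 36 members positive, and had 0.11, 0.05 and 0.02 at 2, 4 and 6 h. Its member with the largest mean was negative: Hspa1b read 0.64, -0.72, -1.08 and -1.04, and its features differed, one at 0.68, 0.10, 0.13 and -0.14 and the other at 0.61, -1.54, -2.29 and -1.93. The phosphatase and kinase list was negative at 1 h (median -0.09, with Ppp3r1, the regulatory subunit of calcineurin, at -1.21) and between 0.09 and 0.11 at the later times. Antioxidant genes included Srxn1, which read 1.04 at 1 h and -0.04 at 2 h, and Gsta4, which read -0.12 and 0.52.

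The negative list was that of choroid plexus markers, a tissue next to the hippocampus (10 genes, adjusted p = 0.045, 0.53 with an estimated correlation), with medians of -0.12, -0.23, -0.14 and -0.11. Its call was also lost with ranks, with equal spread of the arrays, without low features and with 1 feature per gene. Transthyretin, Ttr, read -0.20, -0.90, -0.60 and -0.70. Kl averaged -0.02, -1.42, -1.57 and -1.64, but 1 of its features read 0.20, -2.64, -3.03 and -3.18 and another -0.24, -0.20, -0.11 and -0.09. Over all genes 0 of the 10 markers passed, and 2 passed adjusted over the list alone.

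**Figure D3:**
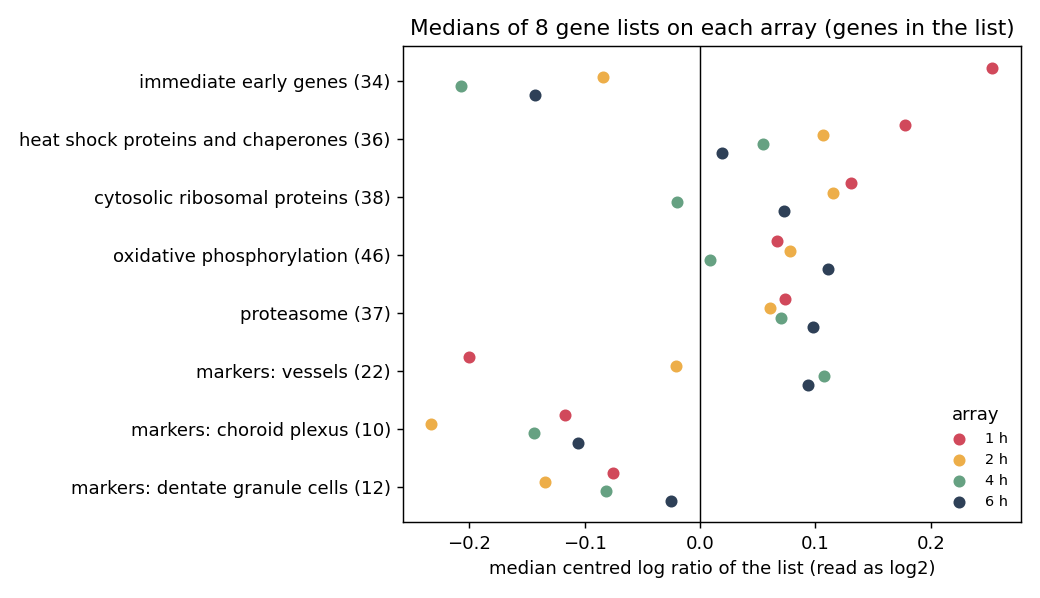
Points give the median centred log ratio (horizontal axis, read as log2) of 8 gene lists on the arrays of 1, 2, 4 and 6 h, with the number of genes in brackets. Proteasome medians lie between 0.06 and 0.10 on all 4 arrays, and the immediate early genes and vessel markers lie on opposite sides of 0 at 1 and 4 h.

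Vessel markers were the other list with a slope past the threshold (22 genes, positive, adjusted p = 0.0405, 0.793 with an estimated correlation and 0.26 without the 1 h array). Their medians were -0.20, -0.02, 0.11 and 0.09, and the endothelial junction gene Cldn5 read -1.05, 0.38, 0.00 and 0.05. Flt1, a receptor for vascular growth factors, ran the other way, from 0.13 at 1 h to -0.38 at 6 h. No vessel marker passed alone in the slope fit, over all genes or adjusted over the list alone. Glutamate receptor and scaffold genes, which include the NMDA receptor subunits that MK-801 acts on, did not pass in either test (adjusted p = 0.946 for the mean and 0.113 for the slope). Their median was -0.20 at 1 h with 4 of 23 positive, at percentile 0.70 of random lists, and 0.15 at 2 h with 15 positive, at percentile 99.9. The NMDA receptor subunit gene Grin2a read -0.20, -0.35, 0.78 and 0.48 at 1, 2, 4 and 6 h, and Grin2b read 0.41, 0.25, -0.23 and 0.00, while another Grin2b feature, without a value at 4 h, read -0.44 at 1 h and 0.55 at 6 h. The granule cell transcription factor Prox1 read -0.57, 0.04, 0.60 and 0.21. Of the genes induced by glucocorticoids, Fkbp5 read 0.37, -0.23, -0.30 and -0.01, and the 2 features of Sgk1 averaged -0.17, -0.07, 0.06 and 0.18, with 0.12 and -0.25 for the single features at 2 h.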

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

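The tests in this part were chosen after the values they bear on had been seen, except the one that leaves out features near low ones. Each time has 1 array, so the 4 arrays were taken as a set and 49 measures (array measures, list medians, Gapdh and the genes always included) were searched for an array far from the other 3. In 6 of them an array was, and it was the 1 h array in 5. For 1 measure of independent normal values chance gives about 1 in 20. The 49 measures share the arrays and some share genes, so 1 odd array can flag many, and their count cannot be set against that rate. The mean correlation of the 1 h array with the others was -0.142, against 0.287 to 0.361 for the rest. Gapdh was -0.259 at 1 h, and the phosphatase and MAP kinase list had a median of -0.0887 there. Fos stood at 0.636 and Junb at 0.349 at 1 h. The Fos value is the mean of features that differed, at 1.17 and 0.11. The feature at 1.17 had number 15860, near a low Hspa1b feature with number 15862. The histone list had its odd array at 2 h, with a median of -0.215. The slope with time differed from that of other genes for the immediate early genes (adjusted p = 0.000795, camera) and for the vessel markers (adjusted p = 0.0405), and both calls were lost with an estimated correlation (adjusted p = 0.793 for each).

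The first pattern is the set of 200 features at or under -1.5 at 2, 4 or 6 h, against 3 at or above 1.5. Of the 200, 109 were this low on 2 or more of those 3 arrays, and 130 had a value at 1 h. A lower transcript of the gene is argued against for 98 genes with a low feature and another feature that was not low. Their low features had a median of -2.56 and the others 0.046 (95% bootstrap interval 0.016 to 0.10). The others lay above -1.5 by this choice, so part of the contrast is built in, though values near 0 were not required. Genes with low features alone were left out, and for them a lower transcript stays open. A local disturbance of the slides may contribute, since 30% of low features had a low neighbour by feature number, against at most 10% in 10000 random placements. That feature numbers follow the place on the slide is an assumption, and spots made from 1 batch of clones or related sequences would also be neighbours. Cross-hybridisation or a wrong annotation of single features stays open and was not tested.

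The second pattern is the 1 h array, which runs apart from the other 3. A turned sign at 1 h cannot be decided. The correlation of 1 h with the mean of the others was -0.169 (95% bootstrap interval -0.192 to -0.146), below 0 as for a turned array. It was weaker than the correlations among the rest, which averaged 0.564. A turned array would reach that size only if the 1 h array shared the signal of the others, which is not known. Features low at later times had a median of -0.0091 at 1 h, with 67 of 130 negative, and lean neither way. A signal of single features shared by the 2, 4 and 6 h arrays may account for much of what these share, because different features of a gene correlated at 0.254 (interval 0.185 to 0.326, 901 pairs) over the mean of those arrays, under the value of 0.398 set as the bound from its reliability of 0.795. The correlation is above 0, so part of the shared signal is that of genes. At 1 h alone the same pairs correlated at 0.143 (interval 0.075 to 0.206), also above 0. The pairs were features made from different sequence records, so different transcripts or a wrong annotation would also lower these correlations. A batch of hybridisations cannot be told apart from time, with 1 array per time: the 1 h array shared its exact 0 values with others at a phi of at most 0.506, against 0.596 to 0.836 among the rest. A response that differs between 1 h and later times stays open, untested.

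The third pattern is the immediate early gene list, positive at 1 h and negative later. Low or neighbouring features are argued against as the whole cause: without every feature within 5 numbers of a low one, the slope of the list had an adjusted p of 0.00121 over 34 genes, as many as before, with the preset correlation. With an estimated correlation the list's slope does not pass even with all features (adjusted p = 0.793). A larger share of granule cells in 1 channel at 1 h cannot be told apart, because the 12 granule cell markers spread too widely (median -0.0751, interval -0.267 to 0.349, against 0.253 for the list). The trend rests on the 1 h array (camera, adjusted p = 0.93 without it). A turned sign of that array, which cannot be decided, would make the median of the list negative at 1 h as well. No change of sign between 1 h and the later times would then remain. Handling, the shock named in the labels, a dye effect that differs between arrays, and a response to MK-801 that changes with time also stay open, untested.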

How the results depend on the processing

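Exact 0 read as a value, features at or under -1.5 left out, 1 feature per gene and the lists with time were chosen after seeing the data. No paired analysis was possible because each time has 1 array and the comparison lies within it. The count of 0 genes for the mean over the 4 times became 14 with values on at least 3 arrays, 11 with quantile normalisation, 1793 with array weights, 825 without the 1 h array and low features, and 0 to 856 with each array left out (856 without 1 h). The 14 and the 11 were all negative. For the slope the range was 0 to 12 (12 without 6 h) and for late against early times 0 to 1329 (1329 without 2 h, where the spread comes from the 4 and 6 h arrays alone). With the other alternatives the count stayed 0 in limma. The mean ratio of Pdlim5 turned to -0.0099 with values on at least 3 arrays, where more features enter, and that of Atp6v1a to -0.11 with exact 0 read as a value, where a feature at exact 0 at 1 and 2 h enters. With a threshold of 1.5 times the counts of genes with values on all 4 arrays at 1, 2, 4 and 6 h were 134, 33, 102 and 51 positive and 231, 115, 171 and 127 negative. With equal spread of the arrays and the threshold of 2 times, the counts that moved by over 1.5 times were 2 positive and 6 negative at 1 h, 11 positive at 4 h and 55 negative at 6 h. Lists over the 4 times numbered 7, 0 with an estimated correlation and 4 to 6 with each array left out. Lists with time numbered 2, 0 with an estimated correlation, 5 on ranks, 5 with equal spread, 4 with 1 feature per gene and 0 to 5 with each array left out (0 without 1 h). Apart from the alternatives that enter more features or fewer arrays, the cause of these differences was not tested. Random lists matched on level were not run, since the table holds no intensities, and signal over background is unknown.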

Other observations

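Several lists outside the calls on all 4 arrays had medians far from those of random lists at single times, which is a description of these arrays with no test. Cholesterol biosynthesis genes had a median of 0.25 at 1 h with 9 of 11 positive, at percentile 99.7, led by Msmo1 (0.60), and 0.00 at 4 and 6 h. Blood markers were positive for 7 of 7 genes at 1 h (median 0.27, percentile 99.2). Markers of newborn neurons and progenitors had medians of -0.16 at 4 h and -0.11 at 6 h (percentiles 0.48 and 1.93). Markers of the thalamus and other forebrain neighbours, listed to follow the tissue taken, had medians of -0.16 and -0.12 at the same times (percentiles 0.84 and 1.84), and choroid plexus markers were negative at these times too (-0.14 and -0.11). Among the newborn neuron markers, Marcksl1, a gene of growing neurites, averaged -0.27, -0.34, -0.59 and -0.47 at 1, 2, 4 and 6 h over features that differed, one at -0.33, -0.48, -0.95 and -0.88 and the other at -0.22, -0.20, -0.24 and -0.05. Synaptic vesicle genes ran from -0.13 at 1 h to 0.16 at 6 h (percentiles 7.59 and 99.8), with Stx1a at -0.40 and 0.54. In camera their slope had an adjusted p of 0.0588 (0.793 with an estimated correlation). Without the 1 h array their mean passed (camera, adjusted p = 0.0466, 0.703 with an estimated correlation). Astrocyte markers had 17 of 24 positive at 6 h (median 0.11, percentile 99.0).

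Clock genes showed no shift as a list (adjusted p = 0.652 for the mean, camera), while single members were far from 0: Dbp, a clock output gene, read 0.84, -0.11, -1.51 and -0.89 at 1, 2, 4 and 6 h, and Per1 stayed between -0.48 and -0.42. The glucocorticoid receptor gene Nr3c1 read -0.80, -0.15, -0.28 and -0.22. The microglial genes Tyrobp, Ctss and Fcer1g were positive on all 4 arrays (means 0.37, 0.26 and 0.23), and the microglial list as a whole had medians between -0.03 and 0.03.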
